A study of Homo sapiens with 12 samples.

How the data were processed

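RNA of the human prostate cancer cell line PC3 was sequenced in 12 libraries. Per the labels, total RNA was extracted with TRIzol and the libraries were made with an mRNA library kit from BGI. The libraries form 4 groups of 3: cells given PBS (BLANK), silver nanoparticles (AgNPs), DOC, or AgNPs and DOC together (COM). The labels give DOC only as an abbreviation and state no dose, exposure time or batch. They do not say that the replicates were separate cultures, so each p-value measures the spread between these libraries.

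The authors named HISAT2, Bowtie2 2.2.5, RSEM and the genome build GRCh38, without saying which step used which tool. The deposited table holds 221796 transcript rows, of which 177700 are linear transcripts (103539 from RefSeq, 52823 with URS and 21338 with BGIR identifiers) and 44096 are circular RNAs. The deposited read-count columns hold expected counts per transcript, not normalised. The deposited expression columns hold FPKM for linear rows, worked out from the values because the header gives no unit. For circular rows the same columns hold CPM with no length term. The columns of group means were not used here.

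The expected counts of all linear rows of a gene were summed and rounded, which gave 43613 genes, 27206 of them with a symbol. Positions are those of RefSeq genes on GRCh38. Summed linear counts per library ranged from 10996446 to 22769479. A floor of 3 counts corresponded to 0.132 CPM in the deepest library and 0.273 CPM in the shallowest, and covers counting error only.

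Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr by group, and 1 robust quasi-likelihood fit over all 12 libraries with 1 coefficient per group. This kept 19986 genes, with a common biological coefficient of variation of 0.033. The 6 comparisons were AgNPs, DOC and COM each against BLANK, COM against AgNPs, COM against DOC, and the interaction. The interaction is the DOC effect with AgNPs minus the DOC effect without AgNPs, on the log2 scale. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Errors of log2 fold changes are standard errors of the fit, with 3 libraries per group.

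The method was tested on simulated data with 200 genes changed by a known factor and with the spread that the fit assumes. Over the 6 comparisons 72 to 84% of 2-fold changes and 26 to 42% of 1.25-fold changes were recovered, and 0.025 to 0.066% of unchanged genes were called. In the data, all comparisons but the interaction called far more than 200 genes. That loosens the cut on p, so these rates do not carry over to them. Single replicates scattered more than counting error in every group, with chi-square per degree of freedom from 1.45 to 4.77.

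Before the data were examined, 29 gene lists with 556 genes were written, of which 526 are in the table: metallothionein, heat shock, NRF2 antioxidant, ATF4 integrated stress, endoplasmic reticulum chaperone, p53 target, mitosis, DNA replication, tubulin, cholesterol synthesis, hypoxia and glycolysis, NFkB inflammatory, interferon response, pro-apoptotic, anti-apoptotic, autophagy and lysosome, proteasome, nuclear-encoded oxidative phosphorylation, drug efflux, epithelial to mesenchymal, immediate early, homologous recombination, luminal prostate, neuroendocrine, fibroblast, immune, mitochondrial-encoded RNA, ribosomal protein and nuclear-retained RNA. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values for lists are over the lists of 1 comparison. The epithelial to mesenchymal list mixes epithelial genes such as CDH1 and KRT8 with mesenchymal ones such as VIM and FN1. Its direction therefore shows no shift towards either state.

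The rule for named genes was also set before the data were examined. For each treatment against BLANK it takes up to 10 called genes each way by fitted fold change, with an average log2 CPM of at least 1, a symbol without one of the clone prefixes looked for, and no overlap between the replicates of both groups. For the other comparisons it takes 5 each way. It adds up to 4 genes of each list with the smallest adjusted p, and 13 genes in every comparison whatever their result. Genes named below outside this rule were chosen after their values were seen, and the text says so. A gene with under 50% of its counts on RefSeq rows, or with close paralogs, is called uncertain.

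Overlaps of AgNPs and DOC responses share the 3 BLANK libraries. They are given beside 20 simulated pairs of unchanged groups against the same BLANK libraries. These groups were drawn around the mean of those libraries, which leaves out the BLANK error that both responses share. The fits were repeated with DESeq2 1.42.0, RLE factors, no filter, a filter of 1 CPM in 3 libraries, a term for replicate number, a fit of only the libraries of both groups, each library left out in turn, and limma-trend on log2(FPKM + 1). After the data were seen, 4 alternatives were added: RefSeq rows only, all libraries thinned to 10996394 counts, BLANK replicate 1 and DOC replicate 1 both left out, and a comparison of effects that share no library. Circular RNAs were tested separately on their counts with the same edgeR fit. Plots were drawn with matplotlib 3.10.9.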

Results

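Gene expression was measured by RNA sequencing in PC3, a human prostate cancer cell line, after PBS (BLANK), silver nanoparticles (AgNPs), DOC, or both together (COM), with 3 libraries per group. The series title names the combination of AgNPs and DOC, so the comparisons below ask what each treatment changed alone, what each changed in the presence of the other, and whether the combination departed from the sum of both. Summed linear counts were 22573481, 22693620 and 22769479 in BLANK replicates 1 to 3, and 18603100, 19323398 and 19421873 in DOC. They were 13362290, 13196849 and 13049868 in AgNPs and 11053501, 11069928 and 10996446 in COM, so depth differed between groups. The share of counts on RefSeq rows also differed by group, from 86.6 ± 0.36% (SD, n = 3) in BLANK to 85.7 ± 0.35% in AgNPs, 84.8 ± 0.41% in DOC and 83.8 ± 0.15% in COM. In a principal component analysis the groups separated on the first component, which held 67.9% of the variance, and DOC replicate 1 lay apart from the other DOC libraries on the second component (10.4%), at -4.69.

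**Figure D1:**
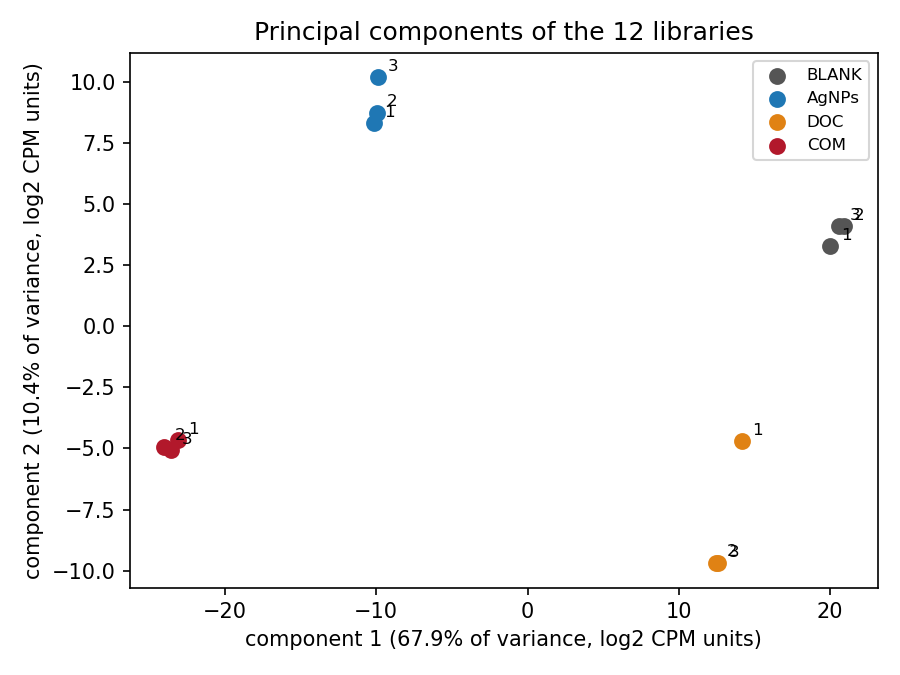
Principal components 1 and 2 of log2 CPM for the 12 libraries, 1 point per library and 1 colour per group. Component 1 (67.9% of the variance) separates the groups, and DOC replicate 1 sits at -4.69 on component 2 (10.4%), above the other DOC libraries.

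AgNPs against BLANK asked what silver nanoparticles alone changed. HMOX1, which breaks down heme and is induced by oxidants and metals (chromosome 22, 35381096 to 35394207), rose 40.5-fold (log2 5.34 ± 0.04 SE, n = 3 per group, edgeR adjusted p = 1.37e-44), from 14.7 ± 0.669 CPM (SD) in BLANK to 594 ± 14.7 CPM. The metallothioneins MT1X and MT2A, which bind metal ions, rose 14.6-fold and 13.8-fold. Here and below both are uncertain because of their paralogs. GDF15, a cytokine secreted by stressed cells, rose 27.8-fold, and ATF3, a stress transcription factor, rose 7.93-fold. Genes of cell division fell, among them MKI67, a marker of cycling cells, 1.79-fold lower. GPX1, a selenium-containing peroxidase that removes hydrogen peroxide, fell most among the named genes, 2.75-fold (log2 -1.46 ± 0.03).

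Over all genes, 6180 of 19986 tested changed after AgNPs, 2983 higher and 3197 lower, and 421 rose and 57 fell at least 2-fold (309 both ways with DESeq2 and 100 with limma-trend). Genes are ranked here and below only among those with an average log2 CPM of at least 1 and no overlap of replicates, so weaker genes that changed more are not named. Within that limit the serine protease HTRA3 (chromosome 4, 8269754 to 8307098) had the largest rise, 97.7-fold (log2 6.61 ± 0.15, adjusted p = 4.07e-29), from 0.282 ± 0.11 CPM in BLANK, near the floor of 3 counts, to 28.3 ± 0.8 CPM. FGF21, a metabolic stress hormone, rose by 4.60 ± 0.28 on the log2 scale, S100P, a calcium-binding protein, by 4.37 ± 0.19, INHBE, an inhibin subunit, by 4.22 ± 0.14, and AKR1B10, an aldo-keto reductase, by 4.08 ± 0.14. Besides GPX1, the largest falls within that limit were of the planar polarity gene PRICKLE2 (-1.07 ± 0.21), the phosphatase CTDSP1 (-1.06 ± 0.05), STARD8 (-1.05 ± 0.15), the DNA helicase PIF1 (-1.03 ± 0.11), the spindle orientation gene SAPCD2 (-0.98 ± 0.05) and CENPA, the histone of centromeres (-0.95 ± 0.08).

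The metallothionein list, which also holds zinc exporter SLC30A1 (1.34 ± 0.05), had 3 tested genes, and all 3 rose, also when adjusted over the list alone. All 28 tested genes of the NRF2 list rose (28 also adjusted over the list alone, camera adjusted p = 1.46e-33, median 1.08). Among them were OSGIN1, an oxidative stress response gene (3.16 ± 0.07), and TXNRD1, the thioredoxin reductase (1.28 ± 0.03). Of 23 ATF4 targets, which cells raise when amino acids are short or protein synthesis is stressed, 22 rose and 1 did not pass (22 adjusted over the list alone, camera adjusted p = 1.19e-29). SESN2, which restrains mTORC1, rose by 3.14 ± 0.06, DDIT4, another mTORC1 inhibitor, by 2.62 ± 0.06, and the transcription factor DDIT3 by 2.04 ± 0.09. In the autophagy and lysosome list 14 of 25 rose, 1 fell and 10 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 2.57e-08). The autophagy receptor SQSTM1 was at 1.39 ± 0.03, GABARAPL1, which coats autophagosomes, at 2.38 ± 0.10 and the autophagy kinase ULK1 at 1.15 ± 0.05. Among 15 immediate early genes 10 rose, 3 fell and 2 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.000217). FOS rose 7.19-fold and MYC, a growth regulator, fell by 0.50 ± 0.03.

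Of 31 mitosis genes 30 fell and 1 did not pass (30 adjusted over the list alone, camera adjusted p = 1.3e-23). Among them were the kinetochore gene CENPF (-0.86 ± 0.03), the mitotic kinesin KIF20A (-0.88 ± 0.04), the topoisomerase TOP2A (-0.59 ± 0.03) and the cyclin CCNB1 (-0.62 ± 0.04). Of 32 DNA replication genes 22 fell, 1 rose and 9 did not pass (22 and 1 adjusted over the list alone, camera adjusted p = 8.72e-10). The helicase subunits were lower, MCM7 at -0.92 ± 0.03 and MCM5 at -0.55 ± 0.04. In the cholesterol synthesis list 13 of 24 fell, none rose and 11 did not pass (15 lower and 2 higher adjusted over the list alone, camera adjusted p = 3.7e-06). The sterol reductase DHCR7 was at -0.52 ± 0.04. Of 29 nuclear-encoded respiratory chain genes 17 fell and 12 did not pass (18 adjusted over the list alone, camera adjusted p = 6.22e-06, adjusted p = 0.162 with an estimated correlation). ATP5F1A fell by 0.35 ± 0.03.

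Several lists were split or passed only with the preset correlation. Of 23 heat shock genes 9 rose, 3 fell and 11 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.223 with an estimated correlation). The inducible chaperone HSPA6 rose by 2.94 ± 0.16, its cofactor DNAJB1 by 0.65 ± 0.03 and HSPA1A, uncertain because of its paralog, by 0.51 ± 0.04. Of 24 hypoxia and glycolysis genes 10 rose, 6 fell and 8 did not pass (12 and 6 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.128 with an estimated correlation). The angiogenic factor VEGFA was at 1.07 ± 0.05 (log2) and NDRG1 at 0.72 ± 0.03. Of 27 proteasome genes 12 rose and 15 did not pass (12 adjusted over the list alone, camera adjusted p = 0.00661, adjusted p = 0.328 with an estimated correlation). Of 16 epithelial to mesenchymal genes 8 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.0601 with an estimated correlation). That list mixes epithelial and mesenchymal genes, so its direction shows no shift of state.

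Other lists did not pass camera after AgNPs. Of 17 NFkB targets 7 rose, 3 fell and 7 did not pass (9 and 3 adjusted over the list alone, adjusted p = 0.0501). The chemokine CXCL8 rose by 1.94 ± 0.09 and CXCL1 fell by 0.45 ± 0.05. That list passed with a term for replicate number (0.0416) and RLE factors (0.0458), and without BLANK replicate 2 (adjusted p = 0.0494), AgNPs replicates 1, 2 or 3 (0.0437, 0.0368, 0.015), DOC replicates 2 or 3 (0.043, 0.0411) or COM replicates 1, 2 or 3 (0.0205, 0.0301, 0.0386). Of 17 p53 targets 6 rose, 1 fell and 10 did not pass (6 and 1 adjusted over the list alone, adjusted p = 0.178), while the cell cycle inhibitor CDKN1A rose 4.22-fold. Of 18 pro-apoptotic genes 4 rose, 1 fell and 13 did not pass (4 and 1 adjusted over the list alone, adjusted p = 0.066, but 0.0494 without BLANK replicate 2 and 0.0372 without AgNPs replicate 1). PMAIP1 rose by 1.06 ± 0.06. Of 7 drug efflux genes 3 rose, 2 fell and 2 did not pass (3 and 2 adjusted over the list alone, adjusted p = 0.165). The conjugate transporter ABCC3 was at 1.39 ± 0.05. The remaining tested lists had these counts, higher, lower and not passing: endoplasmic reticulum chaperones 6, 7 and 6, tubulins 2, 5 and 5, interferon response 1, 6 and 17, anti-apoptotic 2, 2 and 5, and homologous recombination 2, 2 and 12. Adjusted over the list alone they had 6 higher and 7 lower, 2 and 5, 1 and 6, 2 and 2, and 2 and 2, and their adjusted p-values were 0.885, 0.209, 0.45, 0.914 and 0.327. For the chaperone, interferon and anti-apoptotic lists the median, mean and test differed in sign (medians -0.04, -0.03 and 0.01; means 0.07, 0.00 and -0.03; tests down, down and up).

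Signs of RNA quality and markers of other cells were measured beside these groups. After AgNPs 1 of 30 ribosomal protein genes rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.327), and of 3 nuclear-retained RNAs 2 rose (2 adjusted over the list alone). NEAT1 rose by 0.79 ± 0.03. The other, MALAT1, rose by 0.38 and is uncertain, with 0.2% of its counts on RefSeq rows. With those rows only it was at 0.25 (adjusted p = 0.435). None of the 13 mitochondrial-encoded RNAs is in the table. Among fibroblast markers 1 rose, 1 fell and 6 did not pass (1 and 1 adjusted over the list alone, adjusted p = 0.788), and all 3 tested immune markers did not pass. Of 3 luminal prostate markers 1 rose and 2 fell, HOXB13 by 0.32 ± 0.03, and of 3 neuroendocrine markers 1 rose; both counts were the same adjusted over the list alone.

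**Figure D2:**
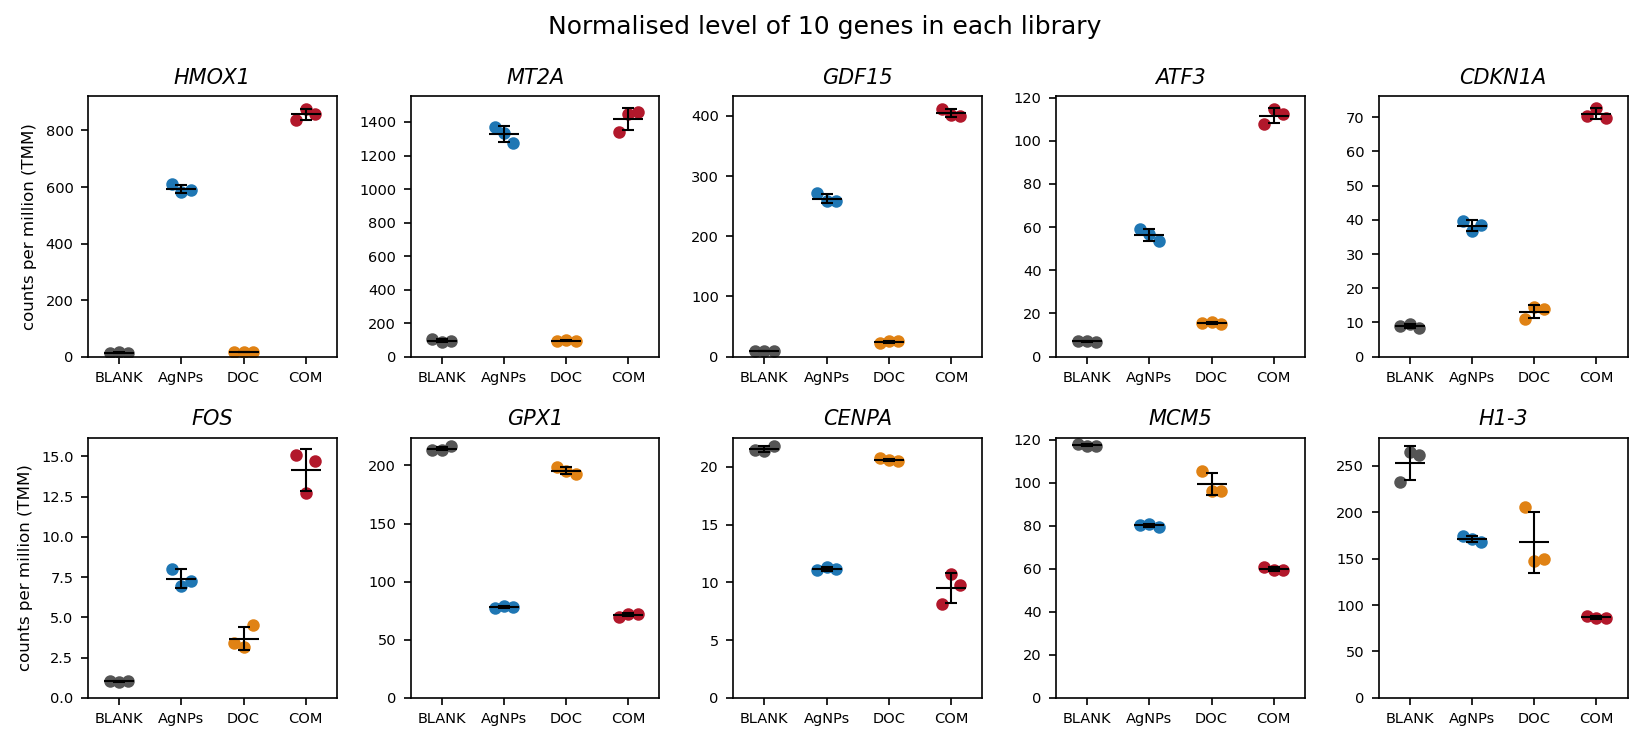
CPM of 10 genes in the 4 groups, with 1 dot per library and the mean with its SD (n = 3). HMOX1 averaged 14.7 CPM in BLANK, 594 CPM in AgNPs, 17.5 CPM in DOC and 856 CPM in COM.

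DOC against BLANK asked what DOC alone changed. The immediate early list rose and the DNA replication list fell. FOS, a growth-responsive transcription factor, rose 3.58-fold (log2 1.84 ± 0.19, n = 3 per group, adjusted p = 8.35e-09), and its relative FOSB rose by 1.22 ± 0.18. GDF15 rose 2.63-fold, ATF3 2.19-fold and BMF, a pro-apoptotic BCL2 family gene, 2.60-fold. TUBA1A, an alpha-tubulin, rose by 0.58 ± 0.05, uncertain because of its paralogs, and the replication genes MCM3 and PCNA fell by 0.32 ± 0.04 and 0.26 ± 0.04. The metallothioneins did not pass, with MT1X at -0.06 ± 0.07 (adjusted p = 0.647) and MT2A at -0.01 ± 0.07 (adjusted p = 0.917).

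DOC changed 3391 of 19986 genes, 1430 higher and 1961 lower, and 153 rose and 6 fell at least 2-fold (21 both ways with DESeq2 and 1 with limma-trend). Without DOC replicate 2 the number changed was 2204, and with limma-trend on log2(FPKM + 1) it was 1090. Protein-coding genes mostly on RefSeq rows made up 45 of the 153 rises and 1 of the 6 falls of at least 2-fold. Genes absent from RefSeq had a median log2 change of 0.15 after DOC and protein-coding genes one of -0.03. Camera compares a list with all other genes, so this shift could add to the list falls below. With RefSeq rows only, which leaves out genes absent from RefSeq, no list fall that passed camera after DOC was lost. By fry, which makes no such comparison, the same lists fell (adjusted p from 4.08e-07 for DNA replication to 0.0202 for the respiratory chain). Both argue against genes absent from RefSeq as the source of these calls. Their share in the size of the falls was not tested. S100P rose by 1.46 ± 0.27. The rises taken within the limit of abundance and overlap also held 3 uncertain genes on few RefSeq rows, LINC03104 (1.64 ± 0.46), LINC01940 (1.11 ± 0.19) and SPACA6-AS1 (1.06 ± 0.23). They held CH507-145C22.1 as well, a clone-based name that the rule was meant to leave out (1.48, adjusted p = 0.000127). The falls taken within it, none of them 2-fold, were of CORO1A, an actin regulator (-0.76 ± 0.18), KCTD8 (-0.75 ± 0.23), IFT70A, a cilium transport gene (-0.66 ± 0.20), C1QTNF8 (-0.59 ± 0.14), and the uncertain MAGEA2B (-0.84 ± 0.29), HHAT (-0.63 ± 0.12), and histone genes H2AC13 (-0.62 ± 0.06) and H1-3 (-0.60 ± 0.12). Calls ended when 1 library was left out for IFT70A (without BLANK replicates 2 or 3 or DOC replicate 2, adjusted p up to 0.0784), KCTD8 (without BLANK replicates 1 or 2 or DOC replicates 2 or 3, up to 0.11), LINC03104 (without any BLANK replicate, AgNPs replicate 3, DOC replicates 1 or 3 or COM replicate 1, up to 0.114) and MAGEA2B (without any library except DOC replicate 2 or COM replicates 1 or 2, up to 0.189). DESeq2 ended the calls of MAGEA2B, KCTD8 and IFT70A (0.059, 0.072 and 0.0712), and limma-trend those of these 3, LINC03104 and SPACA6-AS1 (0.435, 0.166, 0.262, 0.067 and 0.0867). A term for replicate number ended the calls of LINC03104 and MAGEA2B (0.0907 and 0.0848). The call of C1QTNF8 ended after thinning (log2 -0.44) and with limma-trend (-0.33; adjusted p = 0.0818 and 0.0565, and 0.00104 at the lowest of its alternatives). The call of H1-3 ended in a fit of only the BLANK and DOC libraries (adjusted p = 0.102, the highest of its alternatives; the lowest was 7.61e-29).

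Of 15 immediate early genes 8 rose, 1 fell and 6 did not pass after DOC (9 and 1 adjusted over the list alone, camera adjusted p = 3.17e-07). JUNB was at 0.50 ± 0.04 and IER3 at 0.41 ± 0.04. Of 32 DNA replication genes 23 fell and 9 did not pass (27 adjusted over the list alone, camera adjusted p = 2.8e-17, median -0.20). Among them were MCM2 (-0.27 ± 0.04) and MCM4 (-0.24 ± 0.03). Of 16 homologous recombination genes, which repair broken DNA, 6 fell and 10 did not pass (7 adjusted over the list alone, camera adjusted p = 4.34e-05). Among them were BRCA1 (-0.24 ± 0.06) and the exonuclease EXO1 (-0.22 ± 0.04). The call of BRCA1 ended with limma-trend (log2 -0.16, adjusted p = 0.207, the highest of its alternatives; the lowest was 5.64e-05).

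Further lists passed camera after DOC with the preset correlation but not with an estimated one. Of 23 ATF4 targets 9 rose, 4 fell and 10 did not pass (9 and 6 adjusted over the list alone, camera adjusted p = 0.00631, adjusted p = 0.0647 with an estimated correlation). DDIT4 rose by 0.94 ± 0.06, SESN2 by 0.62 ± 0.07 and DDIT3 by 0.53 ± 0.10. Of 12 tubulins, uncertain as paralogs, 4 rose, 1 fell and 7 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00488, adjusted p = 0.0965 with an estimated correlation). TUBB rose by 0.13 ± 0.03, and TUBB3 was at 0.10 ± 0.04 (adjusted p = 0.0711, but 0.0245 without BLANK replicate 3). Of 31 mitosis genes 6 fell and 25 did not pass (8 adjusted over the list alone, camera adjusted p = 0.000751, adjusted p = 0.0965 with an estimated correlation). CENPF fell by 0.20 ± 0.03 and MKI67 by 0.18 ± 0.03, while CCNB1 was at -0.04 ± 0.04 (adjusted p = 0.52) and TOP2A at -0.08 ± 0.03 (adjusted p = 0.0538). TOP2A passed with DESeq2, RLE factors or no filter (0.0487, 0.0272 and 0.0338) and without BLANK replicate 3 or DOC replicate 1 (0.0435 and 0.0105), and its highest value over the alternatives was 0.284. Of 23 heat shock genes 13 fell and 10 did not pass (14 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000342, adjusted p = 0.0965 with an estimated correlation). The mitochondrial chaperone HSPD1 fell by 0.18 ± 0.03. Of 19 endoplasmic reticulum chaperones 10 fell, 2 rose and 7 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.00205, adjusted p = 0.081 with an estimated correlation). PDIA4 fell by 0.22 ± 0.03.

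Of 27 proteasome genes 11 fell and 16 did not pass after DOC (16 adjusted over the list alone, camera adjusted p = 2.52e-06, adjusted p = 0.154 with an estimated correlation). PSMB5 fell by 0.23 ± 0.04. Of 29 respiratory chain genes 9 fell and 20 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000901, adjusted p = 0.291 with an estimated correlation). UQCRC1 fell by 0.21 ± 0.03. Beside these falls, 17 of 30 ribosomal protein genes fell and 13 did not pass (19 adjusted over the list alone, camera adjusted p = 6.9e-08, adjusted p = 0.291 with an estimated correlation). RPL10A fell by 0.25 ± 0.03, and all 3 nuclear-retained RNAs rose (3 adjusted over the list alone), NEAT1 by 0.30 ± 0.03. MALAT1, 1 of the 3, rose by 0.14 and is uncertain, with 0.2% of its counts on RefSeq rows. With those rows only it was at 0.02 (adjusted p = 0.967). Of 3 luminal prostate markers 1 rose, 1 fell and 1 did not pass (1 and 1 adjusted over the list alone), HOXB13 by 0.29 ± 0.03, and of 8 fibroblast markers 2 rose and 6 did not pass (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.277). None of 3 neuroendocrine and 3 immune markers passed (0 and 1 adjusted over the list alone). Of 28 NRF2 genes 5 rose, 2 fell and 21 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 0.277, but 0.0262 with RefSeq rows only). HMOX1 was at 0.26 ± 0.06 (adjusted p = 0.00136), a call that ended when libraries were thinned to the same total of counts (log2 0.22, adjusted p = 0.0801, the highest of its alternatives; the lowest was 0.00118). Of 17 NFkB targets 3 rose, 1 fell and 13 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.246), with CXCL8 at 0.72 ± 0.10, IL1B at 0.62 ± 0.10 and CXCL1 at -0.34 ± 0.04. Of 17 p53 targets 1 rose, 2 fell and 14 did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.788), and the 1 that rose was CDKN1A, by 0.54 ± 0.09. ABCB1, the drug efflux pump, uncertain with 13.3% of its counts on RefSeq rows, was at 1.02 ± 0.39 (adjusted p = 0.0679, but 0.0239 without DOC replicate 3).

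COM against BLANK asked what both treatments together changed. The genes that led after AgNPs alone rose here too. HMOX1 rose 58.5-fold (log2 5.87 ± 0.04, n = 3 per group, adjusted p = 5.12e-46) to 856 ± 20.4 CPM, and HTRA3 rose 147-fold (7.20 ± 0.14). GDF15 rose 42.8-fold, MT1X 16-fold, ATF3 15.7-fold and CDKN1A 7.83-fold. MKI67 fell 2.34-fold and the replication helicase subunit MCM7 2.37-fold, while TUBA1A, uncertain because of its paralogs, rose 2.21-fold.

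The combination changed 9917 of 19986 genes, 5024 higher and 4893 lower, and 1113 rose and 150 fell at least 2-fold (287 both ways with limma-trend). Protein-coding genes mostly on RefSeq rows made up 491 of these rises and 67 of these falls. Beside this, genes absent from RefSeq had a median log2 change of 0.20 and protein-coding genes one of -0.04. Among the largest rises within the limit of abundance and overlap were FGF21 (5.39 ± 0.26), S100P (4.92 ± 0.19), INHBE (4.59 ± 0.14), AKR1B10 (4.33 ± 0.13) and CHAC1, which degrades glutathione (4.26 ± 0.10). Among the falls were PIF1 (-1.80 ± 0.13), C1QTNF8 (-1.67 ± 0.18), GLB1L2 (-1.63 ± 0.26), GPX1 (-1.58 ± 0.04), MYL10 (-1.53 ± 0.20), the stress kinase MAP2K6 (-1.46 ± 0.10) and STARD8 (-1.45 ± 0.17), and the histone genes H1-3 (-1.54 ± 0.13) and H3C13 (-1.45 ± 0.08), uncertain as members of a gene family.

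All 23 ATF4 targets rose after the combination (23 adjusted over the list alone, camera adjusted p = 2.38e-20, median 1.57). SESN2 was at 3.88 ± 0.05, DDIT4 at 3.56 ± 0.05 and DDIT3 at 2.52 ± 0.09. Of 28 NRF2 genes 26 rose and 2 did not pass (27 adjusted over the list alone, camera adjusted p = 8.47e-21). OSGIN1 rose by 3.86 ± 0.07 and TXNRD1 by 1.40 ± 0.03. Of 25 autophagy and lysosome genes 16 rose, 1 fell and 8 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 3.17e-06). GABARAPL1 rose by 3.08 ± 0.09 and SQSTM1 by 1.72 ± 0.03. Of 15 immediate early genes 12 rose, 1 fell and 2 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 2.97e-05). FOS rose by 3.78 ± 0.16 and the phosphatase DUSP1 by 2.02 ± 0.07. Of 31 mitosis genes 29 fell and 2 did not pass (29 adjusted over the list alone, camera adjusted p = 3.18e-17). CENPF fell by 1.26 ± 0.03, TOP2A by 0.87 ± 0.03 and CCNB1 by 0.79 ± 0.04. Of 32 DNA replication genes 29 fell, 2 rose and 1 did not pass (29 and 2 adjusted over the list alone, camera adjusted p = 1.69e-12). MCM5 fell by 0.97 ± 0.04. Of 24 cholesterol synthesis genes 14 fell, 2 rose and 8 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 0.00159). DHCR7 fell by 0.53 ± 0.04. Of 16 homologous recombination genes 10 fell, 1 rose and 5 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 0.00181). FANCA, of the Fanconi repair pathway, fell by 0.40 ± 0.04.

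Lists that passed camera after the combination with the preset correlation alone were the following. Of 24 hypoxia and glycolysis genes 15 rose, 7 fell and 2 did not pass (15 and 7 adjusted over the list alone, camera adjusted p = 0.00273, adjusted p = 0.0627 with an estimated correlation). The lipase inhibitor ANGPTL4 rose 4.01-fold and VEGFA by 1.54 ± 0.04. Of 29 respiratory chain genes 25 fell and 4 did not pass (26 adjusted over the list alone, camera adjusted p = 2.23e-08, adjusted p = 0.0786 with an estimated correlation). CYC1 fell by 0.46 ± 0.03. Of 17 NFkB targets 11 rose, 3 fell and 3 did not pass (12 and 3 adjusted over the list alone, camera adjusted p = 0.0189, but 0.0588 after thinning, adjusted p = 0.186 with an estimated correlation). CXCL8 rose by 2.69 ± 0.09. Of 16 epithelial to mesenchymal genes 10 rose, 3 fell and 3 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0338, but 0.0589 without COM replicate 2, adjusted p = 0.0786 with an estimated correlation). The matrix protein FN1, a mesenchymal member of this mixed list, rose by 0.75 ± 0.07. The list's direction shows no shift of state. Beside these, 20 of 30 ribosomal protein genes fell, 1 rose and 9 did not pass (20 and 1 adjusted over the list alone, camera adjusted p = 0.000175, adjusted p = 0.434 with an estimated correlation), NEAT1 rose by 1.32 ± 0.03, and all 3 tested immune markers rose (3 adjusted over the list alone). Of 3 luminal prostate markers 2 fell and 1 did not pass (2 lower and 1 higher adjusted over the list alone), HOXB13 by 0.87 ± 0.03. Of 3 neuroendocrine markers 2 rose and 1 did not pass (2 adjusted over the list alone), and of 8 fibroblast markers 3 rose, 2 fell and 3 did not pass (3 and 2 adjusted over the list alone, camera adjusted p = 0.938).

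Heat shock genes were split after the combination, 11 higher, 8 lower and 4 not passing of 23 (11 and 8 adjusted over the list alone, camera adjusted p = 0.153). HSPA6 was at 2.69 ± 0.16 and DNAJB1 at 1.04 ± 0.03. Of 18 pro-apoptotic genes 6 rose, 3 fell and 9 did not pass (7 and 3 adjusted over the list alone, camera adjusted p = 0.127). Of its called members BMF was at 2.37 ± 0.16, BBC3 at 1.92 ± 0.20 and PMAIP1 at 1.55 ± 0.06. Of 7 drug efflux genes 5 rose, 1 fell and 1 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.0887). ABCC3 was at 1.47 ± 0.05 and the uncertain ABCB1 at 1.37 ± 0.41 (adjusted p = 0.00581, but 0.0505 without COM replicate 3). TUBB was at -0.01 ± 0.03 (adjusted p = 0.844). Tubulins had 5 higher, 3 lower and 4 not passing of 12 (camera adjusted p = 0.382), and p53 targets 6, 3 and 8 of 17 (0.326).

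**Figure D3:**
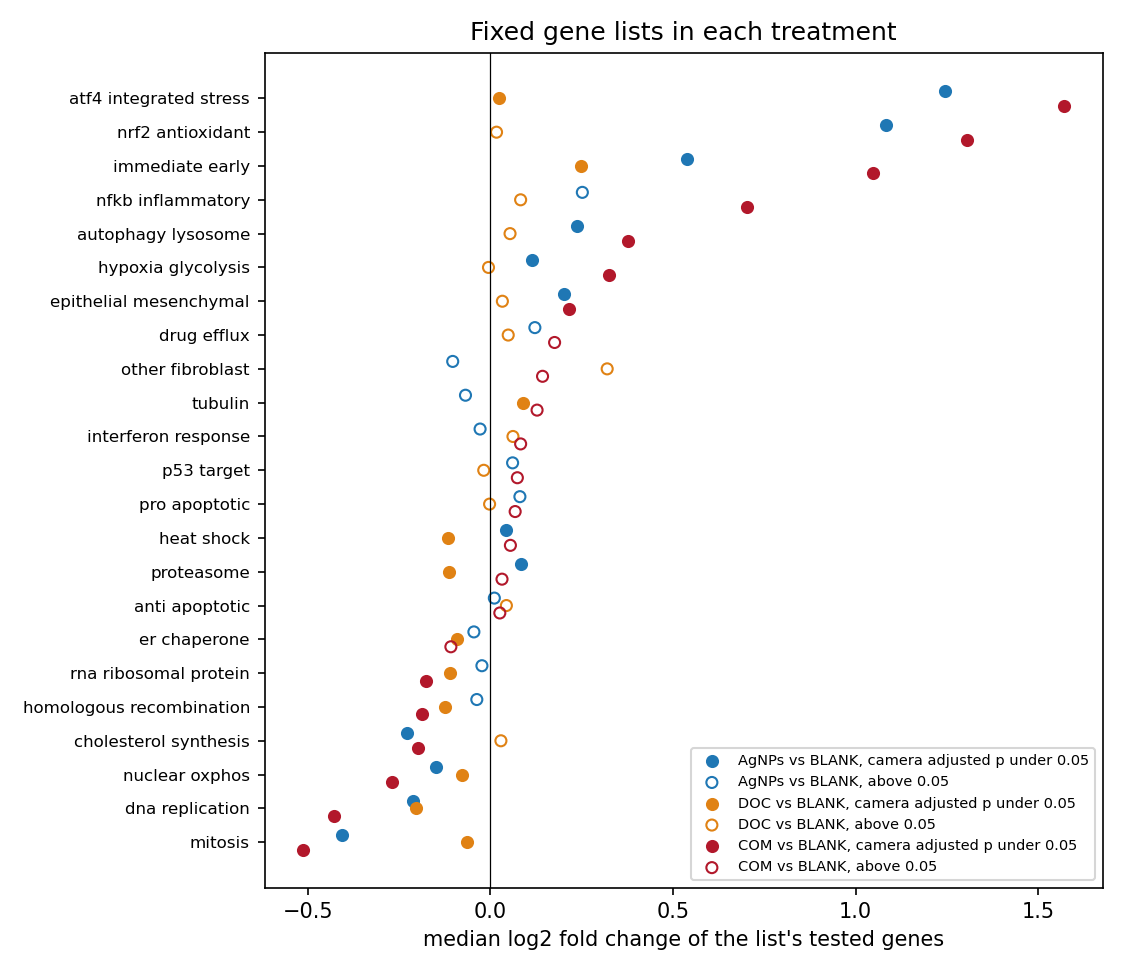
Median log2 fold change of the fixed gene lists with at least 5 tested genes, for AgNPs, DOC and COM each against BLANK. Filled points have a camera adjusted p under 0.05. The NRF2 list lies at 1.08 after AgNPs and the ATF4 list at 1.57 after COM.

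COM against AgNPs asked what adding DOC to AgNPs changed. DDIT4 rose by 0.94 ± 0.04, ATF3 by 0.98 ± 0.05, CDKN1A by 0.89 ± 0.06 and GDF15 by 0.62 ± 0.03 (n = 3 per group, adjusted p = 1.92e-17, 3.27e-17, 4.25e-13 and 3.38e-16). TUBA1A rose by 0.75 ± 0.05 and PMAIP1, a pro-apoptotic gene, by 0.49 ± 0.06. The lists of CDKN1A and PMAIP1 did not pass camera. The p53 targets had 4 higher, 1 lower and 12 not passing (camera adjusted p = 0.65), and the pro-apoptotic genes 5, 2 and 11 (0.176). HMOX1 rose by 0.53 ± 0.03, whereas the uncertain HSPA1A was at 0.02 ± 0.04 (adjusted p = 0.776). MKI67 fell by 0.39 ± 0.03 and MCM5 by 0.42 ± 0.05.

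In this comparison 4369 genes changed, 1973 higher and 2396 lower, and 144 rose and 27 fell at least 2-fold (18 both ways with DESeq2 and 13 with limma-trend). Within the limit of abundance and overlap the largest rises were of DANT1 (2.12 ± 0.17, uncertain, on rows outside RefSeq), the muscle protein gene CMYA5 (1.33 ± 0.23), the nuclear receptor NR4A2 (1.29 ± 0.24) and the carboxypeptidase CPA4 (1.14 ± 0.19). The falls taken within it were of GLB1L2 (-1.25 ± 0.28), ACTL10 (-1.01 ± 0.27), the uncertain histone gene H1-3 (-0.98 ± 0.14) and the receptor GPR85 (-0.97 ± 0.26, adjusted p = 0.00494, but 0.0588 without COM replicate 2). MT1X was at 0.13 ± 0.04 (adjusted p = 0.0111). Its call was lost without AgNPs replicates 2 or 3 or COM replicates 2 or 3 (adjusted p up to 0.0952) and with limma-trend (0.284). CCNB1 fell by 0.17 ± 0.04 (adjusted p = 0.00609, but 0.0521 without AgNPs replicate 1). Protein-coding genes mostly on RefSeq rows made up 33 of the 144 rises and 8 of the 27 falls of at least 2-fold. Genes absent from RefSeq had a median log2 change of 0.16 here and protein-coding genes one of -0.03.

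Of 12 tubulins 9 rose and 3 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000121). TUBB rose by 0.17 ± 0.03, TUBB3 by 0.29 ± 0.04 and TUBB2A by 0.46 ± 0.09, uncertain as paralogs. Of 23 ATF4 targets 17 rose and 6 did not pass (18 adjusted over the list alone, camera adjusted p = 2.38e-12), and of 28 NRF2 genes 15 rose and 13 did not pass (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 7.71e-06). Of 24 hypoxia and glycolysis genes 13 rose, 2 fell and 9 did not pass (14 and 4 adjusted over the list alone, camera adjusted p = 8.55e-05). The glucose transporter SLC2A1 was at 0.43 ± 0.04. Of 15 immediate early genes 10 rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 9.92e-07), and 8 of 25 autophagy and lysosome genes rose and 17 did not pass (13 adjusted over the list alone, camera adjusted p = 0.00045). Of 32 DNA replication genes 24 fell and 8 did not pass (26 adjusted over the list alone, camera adjusted p = 9.9e-13), of 31 mitosis genes 13 fell and 18 did not pass (15 adjusted over the list alone, camera adjusted p = 2.07e-06), and of 16 homologous recombination genes 7 fell and 9 did not pass (11 adjusted over the list alone, camera adjusted p = 7.71e-06). Of 29 respiratory chain genes 16 fell and 13 did not pass (17 adjusted over the list alone, camera adjusted p = 1.47e-06, adjusted p = 0.138 with an estimated correlation), and 14 of 30 ribosomal protein genes fell beside them (18 adjusted over the list alone, camera adjusted p = 3.12e-06, adjusted p = 0.302 with an estimated correlation). All 3 nuclear-retained RNAs rose, the uncertain MALAT1 among them (3 adjusted over the list alone). Of 3 luminal prostate markers 1 fell and 2 did not pass (1 adjusted over the list alone), HOXB13 by 0.54 ± 0.03. Of 3 neuroendocrine markers 2 rose and 1 did not pass (2 adjusted over the list alone), of 3 immune markers 1 rose and 2 did not pass (2 adjusted over the list alone), and of 8 fibroblast markers 1 fell and 7 did not pass (1 adjusted over the list alone, camera adjusted p = 0.717). The proteasome list also passed camera (6 lower and 21 not passing of 27, adjusted p = 0.00436), but not with an estimated correlation (0.302) or RefSeq rows only (0.0827). NFkB targets passed too (5 higher, 2 lower and 10 not passing of 17, camera adjusted p = 0.0458). They did not with an estimated correlation (0.25) or, among others, without AgNPs replicate 3 (0.148).

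COM against DOC asked what adding AgNPs to DOC changed. HTRA3 rose by 6.72 ± 0.14 and HMOX1 by 5.61 ± 0.04 (n = 3 per group, adjusted p = 1.82e-30 and 2.06e-45). MT1X rose by 4.06 ± 0.05, FGF21 by 4.80 ± 0.25 and INHBE by 4.49 ± 0.14. The sodium channel subunit SCNN1G fell by 1.49 ± 0.23, GPX1 by 1.45 ± 0.04, PIF1 by 1.43 ± 0.14, MYL10 by 1.35 ± 0.21 and GLB1L2 by 1.28 ± 0.27.

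Here 7317 genes changed, 3615 higher and 3702 lower, and 550 rose and 85 fell at least 2-fold (177 both ways with limma-trend). All 28 NRF2 genes rose (28 adjusted over the list alone, camera adjusted p = 6.65e-29), and 22 of 23 ATF4 targets rose and 1 did not pass (22 adjusted over the list alone, camera adjusted p = 1.59e-26). Of 31 mitosis genes 29 fell and 2 did not pass (29 lower and 1 higher adjusted over the list alone, camera adjusted p = 8.43e-20). MKI67 fell by 1.05 ± 0.03. Of 24 cholesterol synthesis genes 16 fell, 2 rose and 6 did not pass (17 and 2 adjusted over the list alone, camera adjusted p = 1.63e-05). The epoxidase SQLE fell by 0.44 ± 0.05. DNA replication genes passed too, with 23 lower, 2 higher and 7 not passing of 32 (camera adjusted p = 1.51e-08). Autophagy and lysosome genes had 15 higher and 10 not passing of 25 (camera adjusted p = 1.51e-08). Hypoxia and glycolysis genes had 15 higher, 4 lower and 5 not passing of 24 (camera adjusted p = 1.95e-05). Immediate early genes had 11 higher, 3 lower and 1 not passing of 15 (camera adjusted p = 0.000353). Of 23 heat shock genes 14 rose, 2 fell and 7 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 6.79e-05, adjusted p = 0.0527 with an estimated correlation), with DNAJB1 at 0.97 ± 0.03. Of 27 proteasome genes 16 rose, 1 fell and 10 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.232 with an estimated correlation). PSMA1 rose by 0.29 ± 0.04. Further lists passed camera with the preset correlation alone, and their adjusted p with an estimated correlation is given second. Respiratory chain genes had 20 lower of 29 (4.96e-08 and 0.0805). Genes of the mixed epithelial to mesenchymal list had 8 higher and 3 lower of 16 (0.0148 and 0.0527). Pro-apoptotic genes had 6 higher and 1 lower of 18 (0.017 and 0.0527). NFkB targets had 10 higher and 3 lower of 17 (0.018 and 0.194, but 0.0556 with RefSeq rows only). Of 16 homologous recombination genes 6 fell, 1 rose and 9 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.171). The 1 that rose was BRCA1, by 0.42 ± 0.06. Beside these, 2 of 3 nuclear-retained RNAs rose (2 adjusted over the list alone), NEAT1 by 1.03 ± 0.03, and of 3 luminal prostate markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), HOXB13 by 0.58 ± 0.03. Of 8 fibroblast markers 3 fell and 5 did not pass (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.632).

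The AgNPs and DOC responses overlapped. Among genes higher after AgNPs (2983) and after DOC (1430), 606 were higher after both (315 with DESeq2 and 385 after thinning), against 213.4 for independent responses, and of 3197 and 1961 lower genes 1107 were shared, against 313.7. Simulated unchanged groups shared 0 genes at most, but unchanged groups give almost no calls, so this was fixed in advance. Over all genes the covariance of the log2 fold changes was 0.0637 and the correlation 0.427, and in the simulation 0.001 and 0.029. The simulated groups were drawn around the mean of the same BLANK libraries. This leaves out the BLANK error that both responses share, so the simulation gives no baseline for the overlap or the correlation. Part of the excess over independent responses may come from the shared BLANK libraries, and genes are not independent replicates. GDF15, ATF3, FOS, CDKN1A and CXCL8 were among the genes higher after both, and 170 genes were called in opposite directions, the uncertain HSPA1A among them, higher after AgNPs and lower after DOC. HMOX1, MT1X and MT2A, which rose strongly after AgNPs, were at 0.26, -0.06 and -0.01 on the log2 scale after DOC. In comparisons that shared no library, 2098 genes passed both in the DOC effect without AgNPs and in that with AgNPs, 16 of them in opposite directions, and 4945 passed in both AgNPs effects, 6 in opposite directions.

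The interaction asked whether the combination departed from the sum of the single effects on the log2 scale. Among the genes above the sum were the secreted STC2, by 0.36 ± 0.04, the transcription factor ATF4 by 0.29 ± 0.04 and the asparagine synthetase ASNS by 0.33 ± 0.05 (n = 3 per group, adjusted p = 4.51e-06, 0.000101 and 0.000182). The antioxidant gene SRXN1 exceeded it by 0.42 ± 0.06, the glucose transporter SLC2A1 by 0.39 ± 0.06, the endoplasmic reticulum gene HERPUD1 by 0.47 ± 0.06 and the chaperone cofactor DNAJB1 by 0.32 ± 0.04. GDF15 rose less than the sum, at -0.77 ± 0.07 (adjusted p = 3.51e-08). MKI67 was at -0.21 ± 0.04, which means that it fell more than the sum.

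The interaction passed for 221 of 19986 genes, 146 above and 75 below the sum, 12 and 4 of them by at least 2-fold (4 both ways with DESeq2 and 5 with limma-trend). Leaving out AgNPs replicates 1, 2 or 3 gave 144, 115 or 131 genes, and leaving out COM replicates 2 or 3 gave 119 or 136, while limma-trend on log2(FPKM + 1) gave 56, and the number at 2-fold was 10 without AgNPs replicates 1 or 2 or COM replicate 3. Of 23 ATF4 targets 9 exceeded the sum, 1 was below and 13 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 8.82e-08, median 0.22). Of 24 hypoxia and glycolysis genes 5 exceeded it and 19 did not pass (13 adjusted over the list alone, camera adjusted p = 2.21e-09). VEGFA was at 0.32 ± 0.06, and of 28 NRF2 genes 5 exceeded it and 23 did not pass (8 adjusted over the list alone, camera adjusted p = 1.01e-06), with GCLM, which makes glutathione, at 0.34 ± 0.06. Of 25 autophagy and lysosome genes 4 exceeded it and 21 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00114), SQSTM1 by 0.26 ± 0.04. None of the 24 cholesterol synthesis genes passed (0 adjusted over the list alone, camera adjusted p = 0.606).

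Further lists passed camera in the interaction with the preset correlation alone. Of 23 heat shock genes 4 exceeded the sum and 19 did not pass (7 adjusted over the list alone, camera adjusted p = 5.18e-05, adjusted p = 0.0911 with an estimated correlation). Of 31 mitosis genes 3 lay below it and 28 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00291, adjusted p = 0.147 with an estimated correlation). None of the 12 tubulins passed (1 adjusted over the list alone, camera adjusted p = 0.00972, but 0.0518 without COM replicate 2, adjusted p = 0.144 with an estimated correlation). None of the 29 respiratory chain genes passed (0 adjusted over the list alone, camera adjusted p = 0.00634, adjusted p = 0.368 with an estimated correlation), and the list was lost without BLANK replicate 1 (0.0868), AgNPs replicate 3 (0.056) or DOC replicate 1 (0.0569). CDKN1A was at 0.35 ± 0.11 (adjusted p = 0.131), MT1X at 0.19 ± 0.08 (adjusted p = 0.381), ATF3 at -0.15 ± 0.09 (adjusted p = 0.615) and TXNRD1 at 0.09 ± 0.04 (adjusted p = 0.443).

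**Figure D4:**
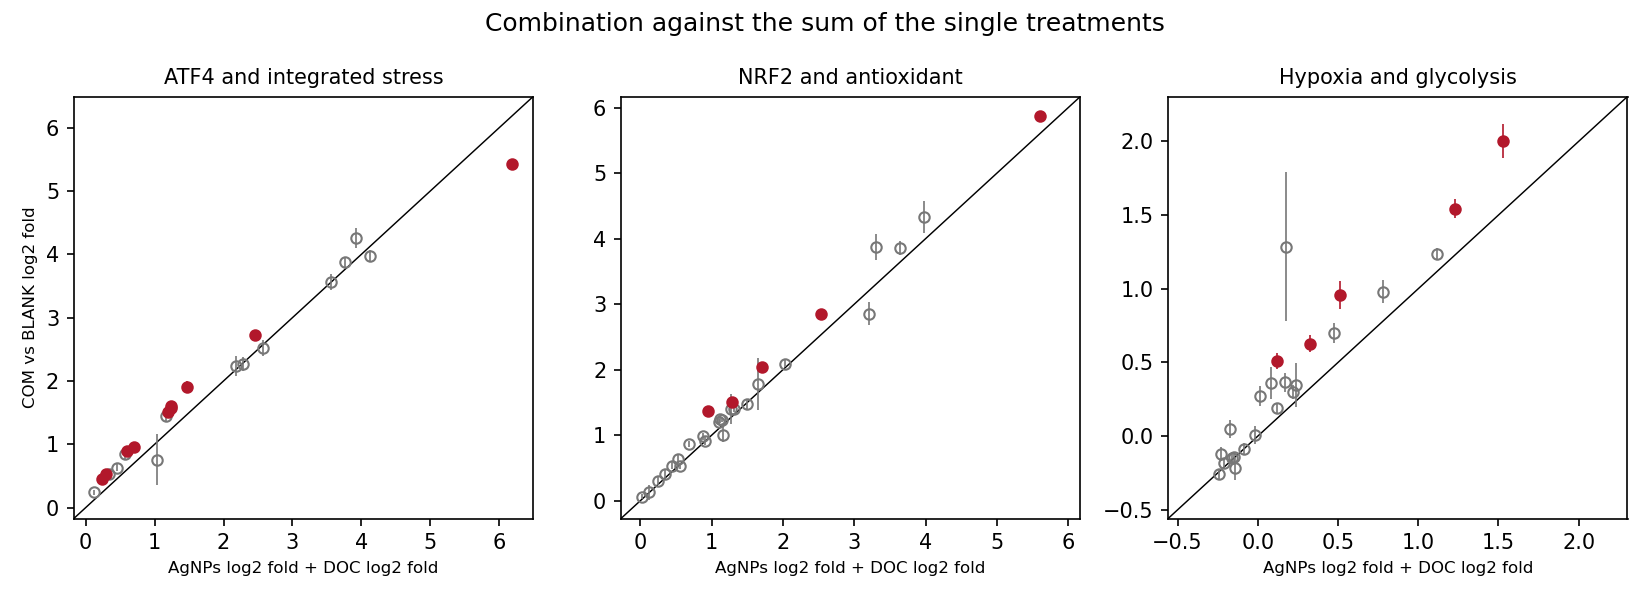
Sum of the log2 fold changes after AgNPs and after DOC (x axis) against the log2 fold change after the combination (y axis) for genes of the ATF4, NRF2 and hypoxia lists; the line marks equality, bars are the SE of the interaction and red points have an interaction adjusted p under 0.05. GDF15 lies below the line by 0.77 ± 0.07.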

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

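The tests of rows outside RefSeq, of RNA of BLANK cells in DOC replicate 1 and of a difference shared with BLANK replicate 1, and the fits with RefSeq rows only, with thinned counts or without BLANK and DOC replicate 1, were chosen after the results were seen.

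The effect of DOC differed with and without AgNPs, by the interaction test of edgeR, for 221 genes. Of 100 splits of the 12 libraries, 4 gave as many genes, the real split included, and the other 3 called 694, 1819 and 2795 genes, several times the real number, which points to a structure of the samples. Such splits mix the AgNPs and DOC effects into the groups and widen their spread, so this count does not say whether chance can be excluded for the interaction. Those 3 splits had 3, 1 and 5 of the 6 AgNPs-treated libraries on the plus side, against 3 in the real split.

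Among genes of the fixed lists, log2 departures above the sum were 0.36 for STC2, 0.29 for ATF4, 0.33 for ASNS, 0.42 for SRXN1, 0.34 for GCLM, 0.23 for FTL, 0.27 for HMOX1, 0.39 for SLC2A1, 0.32 for VEGFA, 0.44 for EGLN3 and 0.30 for KDM3A. They were 0.32 for DNAJB1, 0.39 for HSPB8, 0.14 for HSPA8, 0.21 for HSPA1A, 0.47 for HERPUD1, 0.17 for HSPA5, 0.26 for SQSTM1, 0.28 for TFE3, 0.37 for GLA, 0.21 for MAP1LC3B, 0.22 for TNFRSF10B, 0.45 for DUSP1, 0.27 for KLF4 and 0.24 for NEAT1. Departures below the sum were -0.77 for GDF15, -0.91 for FOS, -0.21 for MKI67, -0.20 for TOP2A, -0.21 for CENPF and -0.26 for HOXB13. GDF15 and FOS rose less than the sum, and the other genes fell more than it. FTL, HSPA1A, HSPA8 and MAP1LC3B have close paralogs or pseudogenes and are uncertain. HSPB8 is uncertain too, because with RefSeq rows only it was at 0.13 (adjusted p = 0.828, the highest of its alternatives; the lowest was 0.00205).

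Outside the fixed lists, the genes taken by the naming rule, which leaves out weakly expressed genes that departed more, had few counts on RefSeq rows and are uncertain: DANT1 (1.92), HHAT (1.37), SEC61G-DT (1.02), SIRT4 (0.84), GRAPL-AS1 (0.74), DUBR (-0.62) and SPRN (-0.59). CH507-145C22.1, a clone-based name that the rule was meant to leave out, was at -2.11. SEC61G-DT lost its call in 10 of 12 fits without 1 library (adjusted p from 0.0332 to 0.19) and SPRN in 6 (0.0156 to 0.12), and of these 8 genes only HHAT and GRAPL-AS1 passed with limma-trend.

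Of the 39 named interaction genes that passed, leaving out 1 library ended the calls of several, most with AgNPs replicate 2 left out (16 calls, adjusted p up to 0.232) and COM replicate 2 left out (14, up to 0.132). Without BLANK replicates 1, 2 or 3 the calls ended were 6, 9 or 12 (up to 0.158, 0.144 and 0.117), without AgNPs replicates 1 or 3 they were 8 or 12 (up to 0.19 and 0.166), without DOC replicates 1, 2 or 3 they were 4, 5 or 8 (up to 0.154, 0.127 and 0.149), and without COM replicates 1 or 3 they were 8 or 11 (up to 0.132 and 0.129). FOS lost its call in 9 of 12 such fits (adjusted p from 0.0224 to 0.149), HSPA1A in 11, HMOX1 in 5 (0.0228 to 0.12) and EGLN3 in 1, without AgNPs replicate 2 (0.0544), while STC2, ATF4, ASNS, SRXN1, GCLM, SLC2A1, VEGFA, KDM3A, DNAJB1, HERPUD1, SQSTM1, MKI67, HOXB13, NEAT1 and GDF15 passed in all 12. With limma-trend on log2(FPKM + 1) FOS was at -0.12 and after thinning at -0.56 (adjusted p = 0.851 and 0.519, against 0.0218 as the lowest of its alternatives). Of the genes given above from the fixed lists only STC2, ATF4, ASNS, SRXN1, SLC2A1, DNAJB1, HERPUD1, GDF15 and HOXB13 passed with limma-trend. With a term for replicate number the calls of HSPA8, FTL and MAP1LC3B ended (adjusted p = 0.052, 0.0714 and 0.0646; over all alternatives they ranged from 0.0033 to 0.321, 7.08e-05 to 0.335 and 0.0122 to 0.233).

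Lists that departed from the sum had camera adjusted p-values of 2.21e-09 for hypoxia and glycolysis, 8.82e-08 for ATF4 targets, 1.01e-06 for NRF2 genes, 5.18e-05 for heat shock, 0.00114 for autophagy and lysosome and 0.00972 for tubulins, all above the sum, and 0.00291 for mitosis and 0.00634 for respiratory chain genes, both below it. The heat shock, mitosis, tubulin and respiratory chain calls were lost with an estimated correlation (adjusted p = 0.0911, 0.147, 0.144 and 0.368 with an estimated correlation).

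Circular RNA rows, which no comparison of the report used, also changed by edgeR: 259 after AgNPs, 19 after DOC and 2091 after the combination, of 30954 tested. At an unadjusted p under 0.05 they were 3805, 1903 and 7596, where a share of 0.05 of the rows would pass without any change. DESeq2 called 418, 158 and 2656. Circular rows held 12.2 to 15.8% of all counts per library. Whether those reads came from circular RNAs or from linear transcripts was not tested in these libraries, made with an mRNA kit.

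In each comparison of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. The real split called 6180 genes after AgNPs and the highest other 1, and after DOC 3391 and 34. After the combination it called 9917 and the highest other 0, for COM against AgNPs 4369 and 1, and for COM against DOC 7317 and 0. In each, 1 split of the 10 gave as many genes, the real one.

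After the combination most genes changed at least 2-fold were increases, 1113 against 150. Protein-coding genes mostly on RefSeq rows made up 491 of the rises and 67 of the falls. Genes absent from RefSeq had 232 rises and 38 falls, and RefSeq genes mostly on other rows 260 and 21. Other RefSeq genes had 130 and 24. Lower depth in the treated libraries was argued against, because with all libraries thinned to 10996394 counts 88% of such genes were still increases. Rows outside RefSeq as the cause were argued against too, because with RefSeq rows alone 87.9% were. A response of the cells to the combination stays open as a hypothesis, and genes without a RefSeq entry rose in the median by 0.20, so an effect of RNA processing or library composition was not tested.

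The ATF4 list lay above the sum of the single effects, with a median of 0.22 and a mean of 0.13. Of its 23 genes 9 exceeded the sum, 1 was below and 13 did not pass. Lower depth was argued against, because after thinning the median was 0.23 (camera adjusted p = 1.9e-06). The libraries that stand apart were argued against, because without BLANK replicate 1 and DOC replicate 1 the median was 0.20 (camera adjusted p = 1.68e-08). A joint response to both treatments may account for it and stays a hypothesis, as does a departure from additivity on the log2 scale that another scale would not show, which was not tested.

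DOC replicate 1 stood apart from the other DOC libraries, with a slope on the DOC effect seen with AgNPs of 0.379, against 0.684 and 0.63 in DOC replicates 2 and 3. RNA of BLANK cells as the whole cause was argued against, because the circular share of its counts was 15.76%, 4.55 SD above the mean of the BLANK and other DOC libraries, which lay between 12.2 and 13.7%. A part from such RNA cannot be told apart. Of the variance of its deviation, 38.2% lay along the difference of BLANK from the other DOC libraries, between the bounds set for and against. Both measures subtract DOC replicates 2 and 3, so they correlate (0.618) to some degree even without mixing. With AgNPs minus COM, which shares no library with the deviation, the correlation was 0.431. A library difference shared with BLANK replicate 1 cannot be told apart either, as the correlation over genes was -0.277, between its bounds. A weaker response to DOC in that library's cells could also give the slope, and was not tested.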

How the results depend on the processing

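The fits with RefSeq rows only, with counts thinned to 10996394 per library and without BLANK replicate 1 and DOC replicate 1 together were chosen after the data were seen. Numbers of changed genes, called lists and genes shared by both single treatments stayed within 1.5 times the reported ones with RLE factors and with a term for replicate number (20 of 20 counts each). Of the counts of changed genes and called lists from fits that left out 1 library, 207 of 216 did. Same-number correlations of the libraries ran from -0.242 to 0.265 (mean 0.003), and 3 of 12 libraries were closest to 1 of their own number. Between AgNPs and COM they were 0.161, 0.202 and 0.131, so a pairing of those groups was not excluded. For named genes, direction and call held in 345 of 354 with DESeq2, 360 of 361 with RLE factors, 359 of 361 without a filter, 350 of 361 after thinning, 335 of 344 with RefSeq rows only, 322 of 361 with limma-trend on log2(FPKM + 1), and 4182 of 4332 when 1 library was left out. For lists, direction and call held in 106 of 138 with an estimated correlation, where the other 32 calls were lost, and in 108 of 138 with fry, which does not compare a list with other genes. Depth was lowest in COM, with 10996446 to 11069928 counts per library.

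DESeq2 gave 309 genes changed at least 2-fold after AgNPs, 21 after DOC, 18 for COM against AgNPs and 4 in the interaction, and 315 genes higher after both single treatments. The limma-trend fit, whose pseudocount shrinks the folds of weakly expressed genes, gave 100 after AgNPs, 1 after DOC, 287 after the combination, 13 for COM against AgNPs, 177 for COM against DOC and 5 in the interaction at 2-fold, and 1090 genes changed at all after DOC and 56 in the interaction. No filter gave 265 after DOC and 36 in the interaction at 2-fold, as more weakly expressed genes were tested, and the filter of 1 CPM, with fewer, gave 90 after DOC and 107 for COM against AgNPs. Only the libraries of both groups gave 110 for COM against AgNPs at 2-fold. RefSeq rows only gave 72 after DOC, 812 after the combination, 99 for COM against AgNPs and 7 in the interaction at 2-fold. Thinning gave 385 genes higher after both single treatments. With an estimated correlation 7 lists were called after AgNPs, 3 after DOC, 8 after the combination, 8 for COM against DOC and 4 in the interaction, and with fry 19 after AgNPs. The endoplasmic reticulum chaperone list after AgNPs went up by fry (adjusted p = 0.00405) and down by camera, and DUBR reversed to 0.51 in the interaction with RefSeq rows only. Except where the alternative's construction is given, the cause was not tested.

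With 1 library left out, the number of genes changed ranged from 5183 to 6636 after AgNPs, 2204 to 4027 after DOC, 8922 to 10258 after the combination, 3406 to 4946 for COM against AgNPs, 6430 to 7348 for COM against DOC and 115 to 269 in the interaction. At 2-fold the ranges were 438 to 511, 115 to 183, 1216 to 1484, 159 to 203, 624 to 722 and 10 to 22. Lists called ranged from 12 to 14, 11 to 11, 12 to 13, 12 to 13, 14 to 14 and 7 to 9.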

Other observations

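The gene families below, and the tests of them, were chosen after the results were seen, except that SELENOW and SELENOH were named before their values were looked at.

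Histone genes picked by symbol were mostly lower after each treatment. Most of them are replication-dependent, which means that they supply the histones of newly made DNA. Of 55 tested, 33 fell, 1 rose and 21 did not pass after AgNPs, 46 fell and 9 did not pass after DOC, and 50 fell, 1 rose and 4 did not pass after the combination, with medians of -0.23, -0.33 and -0.85 on the log2 scale. After AgNPs the family passed with the preset correlation alone (camera adjusted p = 1.88e-09, and adjusted p = 0.067 with an estimated correlation). Against the BLANK mean, the median in single libraries was -0.21, -0.21 and -0.26 in AgNPs, -0.30, -0.35 and -0.36 in DOC and -0.84, -0.84 and -0.86 in COM, with BLANK libraries between -0.04 and 0.03. In the interaction 15 lay below the sum and 40 did not pass (median -0.24, camera adjusted p = 3.3e-21 over the 4 families, and adjusted p = 0.0102 with an estimated correlation). These genes are close paralogs, so counts of single members are uncertain, and most of their mRNA carries no poly(A) tail, so its yield in an mRNA library depends on the preparation.

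Amino-acid transporters rose with AgNPs: of 13 tested, 10 rose, 1 fell and 2 did not pass (camera adjusted p = 2.14e-08, and adjusted p = 0.0351 with an estimated correlation), among them the cystine importer SLC7A11 at 1.93 ± 0.04 and the serine and alanine carrier SLC1A4 at 1.64 ± 0.07 (n = 3 per group). After DOC 2 rose, 2 fell and 9 did not pass, and in the interaction 6 lay above the sum and 7 did not pass. Of 20 cytosolic tRNA synthetases 10 rose, 5 fell and 5 did not pass after AgNPs, and 12 fell and 8 did not pass after DOC. In the interaction 4 of them lay above the sum and 16 did not pass, SARS1, which charges the serine tRNA, among them at 0.21 ± 0.05.

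A hypothesis was that the fall of GPX1 after AgNPs belongs to a fall of the selenoprotein mRNAs that are most sensitive to selenium supply. It predicted falls of SELENOW and SELENOH of at least 0.5 on the log2 scale, and both fell, SELENOW at -0.87 ± 0.07 and SELENOH at -0.90 ± 0.11 (edgeR adjusted p = 6.55e-13 and 1.09e-05, n = 3 per group). GPX4, a less sensitive one, fell by 0.29 ± 0.04, and TXNRD1 and SEPHS2, which makes the selenium donor, rose by 1.28 ± 0.03 and 0.60 ± 0.04. Over all 19 tested selenoprotein genes 5 rose, 7 fell and 7 did not pass (camera adjusted p = 0.604), so the family as a whole did not move one way. The 3 falls may reflect less selenium available to the cells, but selenium was not measured, and TXNRD1 is also an NRF2 target.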
